A study of Caenorhabditis elegans with 7 samples.

How the data were processed

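The data were 7 poly(A)-selected, stranded, single-end RNA libraries (122 bp reads) from pools of whole worms, 4 fed EV bacteria and 3 fed ufm-1 RNAi bacteria. Per the submitters' processing notes, the authors used cutadapt 2.10, TopHat2 2.1.1, HTSeq 2.01 and DESeq2 (version not listed) with genome build WBcel235. The annotation release, the counting mode and the strand setting are not given in the sources used here. TopHat2 and HTSeq as a pair leave open how reads from near-identical copies were treated, so single members of the ugt, msp and collagen families are uncertain.

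The deposited table has 46934 rows, of which 22416 carry counts in the 7 libraries and 24518, mostly short noncoding RNAs, carry none. Per the file headers, the authors deposited raw counts, normalized counts and a further corrected version of the normalized counts. The deposited counts are whole numbers of reads per gene, not normalized. The authors' normalized signal, given for 18288 genes, equals the count divided by one size factor per library. The other deposited columns carry a further per-gene correction whose method is not given in the sources used here. That correction moved sets 1 and 2 of both groups one way and sets 3 and 4 the other (correlation of the log ratio between libraries at least 0.873 within and at most -0.866 between these sets, over 7223 genes across which it was computed). These sets are called batch A and batch B, and the corrected values were used for nothing else. No fold changes or p-values of the authors stand in the table, so the planned comparison with them was not run.

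All values in the text come from the counts. Totals ranged from 11806261 to 20520930 per library, so that a gene at 1 CPM, a count scaled to library size, rests on few reads and is the least precise. Libraries of a group differed beyond sampling noise in every pair (chi-square per degree of freedom from 4.38 to 30.7), so all 7 were kept as separate samples. The labels describe independent sets of the experiment, each a pool of worms.

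Genes were kept by edgeR's filterByExpr on the group (13459 genes, 99.9% of counts), scaled by TMM and tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust estimation, glmQLFTest, two-sided, Benjamini-Hochberg adjusted p under 0.05). All 7 libraries entered the fit, with the group as the only term. Log2 CPM used a prior count of 2. The standard error is the absolute log2 change divided by the square root of the test's F. The ufm-1 level also had an exact permutation test of log2 CPM over 35 splits.

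The 34 gene lists named in the results were tested with camera (limma 3.58.1) on log2 CPM at a preset correlation of 0.01, adjusted over the lists. Camera was repeated with an estimated correlation, and fry was run beside it. With an estimated correlation 0 of the 34 lists passed in the fits with the group alone, the replicate block or the batch term, and fry's directional test passed 0 lists. Its mixed test passed 1 list with the group alone, UFMylation (adjusted p = 0.00134), 4 with the replicate block and 12 with the batch term. The UFMylation list holds ufm-1, the RNAi target. The smallest edgeR p among its other members, unadjusted and with the group alone, was 0.102 (uba-5), so this pass can rest on the target alone. The lists overlap, for example spp-1 in DAF-16 class II and immunity or fat-5 in DAF-16 class I and lipid metabolism.

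Named genes followed a rule. It takes ufm-1 and the UFMylation list, the largest rises and falls among genes past the threshold, and up to 4 members per list past it, or the 2 with the smallest p as values only. With fewer than 5 genes past the threshold, the 10 with the smallest p are given as values. The value of 1 gene that the rule names is not reported here. The groups, the main design, the lists, this rule and the other settings listed below were fixed before the data were examined. The batch term, the fits within each batch, batch A at an estimated correlation and the fits with a block or batch term that leave out a library were added after.

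The labels give the replicate number as the mark of a set, so the numbers pair the samples. Libraries of a set also deviated together from their group means (correlation across genes 0.306, 0.213 and 0.433 in sets 1, 2 and 3). Libraries of the same batch with different numbers correlated about as much (0.237, 0.337 and 0.404), so these values do not separate set from batch, and the pairing rests on the labels. The fit with the replicate as a block is given beside a result where it changes a call. Alternatives covered scaling (DESeq2 size factors, library totals, upper quartile), low-count filters, DESeq2 1.42.0, limma-voom with quality weights, dispersion estimation without robustness, thresholds, composition genes left out and each library left out.

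The steps were tested on simulated counts for the 13459 genes, 200 of them changed, drawn for the ufm-1 RNAi against EV comparison. The fit with the group alone recovered 36.4% of genes changed 1.5-fold, 70.2% of those changed 2-fold and 94.0% of those changed 4-fold, with 6.41 to 6.65% of calls false. The blocked fit recovered 54.5%, 76.7% and 96.4%, with 9.40 to 11.7% of calls false, above the nominal 5%. Each fit was simulated from the dispersions it had itself estimated, with no set or batch effect. These recoveries therefore do not compare the fits on the same data and do not cover data with batches. Of 20 simulated lists raised 1.2-fold the set test found 20, and of 20 unchanged lists it found 0. Simulated genes were drawn independently, so the set test's result there does not cover correlated genes. Coordinates are from the WBcel235 annotation.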

Results

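RNA was sequenced from pools of whole Caenorhabditis elegans of strain CL2006, which carries a transgene for the human amyloid-β peptide driven in body wall muscle and the roller marker rol-6. The worms grew at 20 °C for 2 generations, either on bacteria labelled EV, which served as the control, or on bacteria expressing double-stranded RNA against ufm-1. They were collected on day 6 of adulthood according to one label field, while another gives only an age of 6 days. The EV group had 4 libraries and the ufm-1 RNAi group had 3, and the number of each library marks an independent set of the experiment. An RNAi library of set 4 was not analysed here. Total gene counts were 11806261, 14694136, 20520930 and 18173566 in EV sets 1 to 4 and 18112338, 18610856 and 15403246 in RNAi sets 1 to 3.

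The first principal component held 43.1% of the variance and separated sets 1 and 2 (batch A) from sets 3 and 4 (batch B), in both groups. The second held 21.9%. On it the RNAi libraries (5.85, 12.2 and 26.6 in sets 1 to 3) lay above the EV libraries (4.25, -13.1, -22.99 and -12.8 in sets 1 to 4), and RNAi set 3 lay far from EV set 3. Transcripts encoded in the mitochondrial genome took 1.61% of the counts in RNAi set 3 (95% exact interval 1.604 to 1.616%, which covers counting error alone, while libraries of a group differed by more than counting error). They took 0.73 to 1.19% in the 4 EV libraries and 1.01 and 1.03% in RNAi sets 1 and 2.

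**Figure D1:**
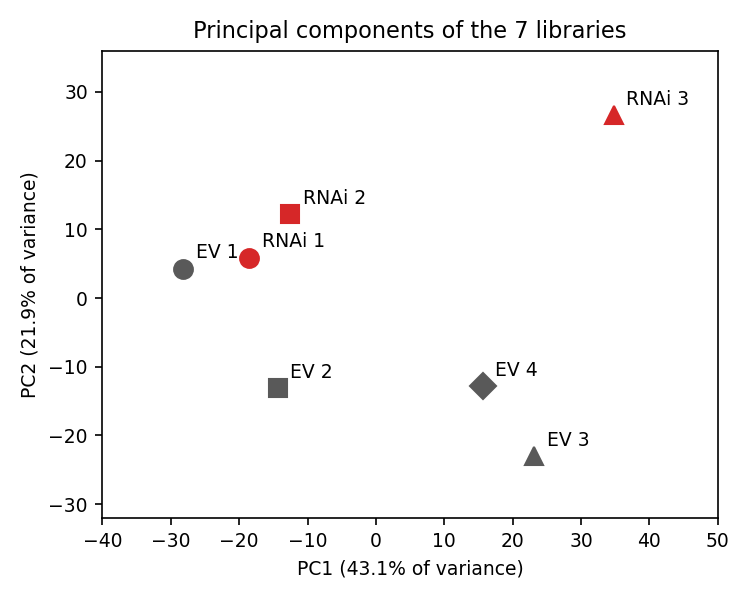
Principal components of log2 CPM for the 7 libraries, with PC1 on the horizontal axis and PC2 on the vertical axis, EV control in grey, ufm-1 RNAi in red and a marker shape for each set. PC1, with 43.1% of the variance, places sets 1 and 2 at the left and sets 3 and 4 at the right, and PC2, with 21.9%, has RNAi set 3 at its upper end.

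The comparison of the groups asks which transcripts differ in worms under this proteotoxic load when the bacteria target ufm-1, which encodes ubiquitin-fold modifier 1, the small protein attached to others in UFMylation. The target itself (WBGene00044324; WBcel235 chromosome III, 7858979 to 7859512, plus strand, 2 exons) was lower in every RNAi library than in every EV library. It stood at 46.6 ± 3.44 CPM (counts scaled to library size; SD, n = 4) on EV and at 25.3 ± 5.17 CPM (SD, n = 3) on ufm-1 RNAi, which is 54.4% of the EV level, with 384 to 1064 reads per library. The log2 change was -0.88 (SE 0.13), and an exact two-sided permutation test over the 35 splits of the libraries gave p = 0.0286, the smallest value this design allows. It was -0.99 within batch A and -0.64 within batch B, and -1.05, -0.92 and -0.73 in sets 1, 2 and 3. Over the 13459 genes tested, edgeR's quasi-likelihood test with the group alone gave an adjusted p of 0.232, while the fit with the replicate as a block gave 0.00996. Adjusted over the list alone, ufm-1 passed among the 7 UFMylation genes. Reads from bacterial double-stranded RNA on worm material would add to the RNAi libraries' ufm-1 counts and cannot be separated here.

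**Figure D2:**
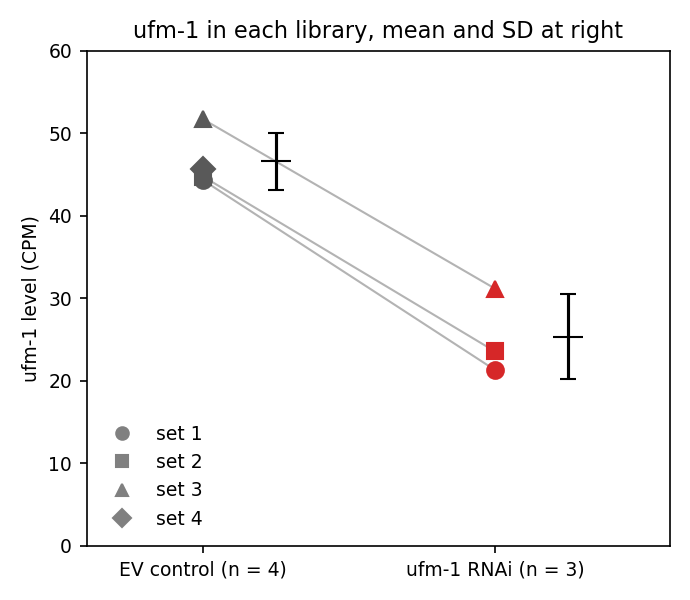
Level of ufm-1 in CPM (vertical axis, from 0) in each EV control (grey) and ufm-1 RNAi (red) library, with lines joining libraries of a set, and mean and SD drawn at the right of each group. The RNAi libraries lay between 21.3 and 31.2 CPM and the EV libraries between 44.3 and 51.7 CPM.

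The other members of the UFMylation list stayed near their EV levels, and none passed. Changes were -0.12 for uba-5, the activating enzyme, 0.05 for ufc-1, the conjugating enzyme, and -0.05 for ufl-1, the ligase. They were -0.04 for ufbp-1, a partner of the ligase, -0.04 for odr-8, a protease of the pathway, and 0.06 for cdkr-3. The log2 standard errors of these genes ranged from 0.06 to 0.13. As a list, UFMylation had a median of -0.04 and did not pass the camera set test (adjusted p = 0.0843).

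Across the transcriptome most changes were small, with 94.9% of genes within 1.5-fold. In the fit with the group alone no gene passed an adjusted p of 0.05 with edgeR (0 higher and 0 lower). At an unadjusted p under 0.05 there were 773 genes higher and 421 lower, 1194 in all, where evenly spread p-values would give 673. Over the 35 splits of the libraries into 3 and 4 this number ran from 89 to 3729. Some wrong groupings, with another mix of batches than the real one, exceeded 1194 (for example 3165 and 1844). The excess over 673 is therefore no measure of an effect of the RNAi. DESeq2 called 8 genes and limma-voom 1. With the replicate as a block, edgeR called 5 genes, of which 4 rose and ufm-1 fell. The genes that rose were ugt-31 and ugt-41, which encode glucuronosyltransferases that couple sugar to small molecules, spp-17, which encodes a saposin-like protein, and T12D8.5, which encodes an uncharacterised protein. Their log2 changes in that fit were 1.11 (SE 0.15) for ugt-31, 0.54 (SE 0.08) for ugt-41, 0.57 (SE 0.08) for spp-17 and 0.65 (SE 0.09) for T12D8.5. Each had an adjusted p of 0.0369 and was higher in 3 of 3 sets. The largest relative change among these was that of ugt-31, from 7.03 ± 1.48 CPM (SD, n = 4) to 15.5 ± 5.01 CPM (SD, n = 3). On WBcel235, ugt-31 lies at chromosome I, 2333338 to 2338693, spp-17 at I, 1016405 to 1017176, ugt-41 at V, 7161068 to 7163595, and T12D8.5 at III, 13625972 to 13626786. Without EV set 2 or RNAi set 2 none of the 5 genes passed. In a blocked fit, a library whose partner is left out carries no information on the group. Leaving out either library of a set is therefore nearly the same check. EV set 4 has no partner, so leaving it out hardly tests the blocked change. Over the 7 blocked fits that each left out a library, the log2 change of ufm-1 ran from -0.995 to -0.810. That of ugt-31 ran from 0.957 to 1.23, of ugt-41 from 0.481 to 0.594, of spp-17 from 0.502 to 0.699 and of T12D8.5 from 0.585 to 0.692. The number of calls went from 5 to 654, 1, 120 and 5 without EV sets 1 to 4, and to 399, 0 and 117 without RNAi sets 1 to 3. T12D8.5 lies outside the rule for named genes and was chosen after its values were seen.

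A term for the batch in place of the replicate, added after the data were seen, called 11 genes higher and ufm-1 lower. Its calls included spp-17, ugt-31, ugt-41 and the glucuronosyltransferase gene ugt-66 (log2 change 0.74, SE 0.11), but not T12D8.5. The other 7 were C42D4.1, which encodes a protein with a DUF148 domain, and the uncharacterised genes Y34F4.2, F08G2.5, F15B9.6, C05D2.8, Y62H9A.3 and F56D6.9. With the group alone, the smallest p values outside ufm-1 belonged to Y34F4.2 (log2 change 1.56, SE 0.23, at 0.795 CPM on EV), F08G2.5 (0.89, SE 0.13), spp-17 (0.61, SE 0.09) and C42D4.1 (0.44, SE 0.07). They were followed by ttr-48, a transthyretin-related gene (0.40), Y62H9A.3 (0.43), Y38H8A.1 (1.097), the girdin homologue grdn-1 (0.46) and Y43F8B.2 (0.42). Each of these was higher in 3 of 3 sets, and none passed in that fit. Without EV sets 1 to 4 the batch fit called 28, 13, 13 and 2 genes, and without RNAi sets 1 to 3 it called 917, 0 and 8.

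**Figure D3:**
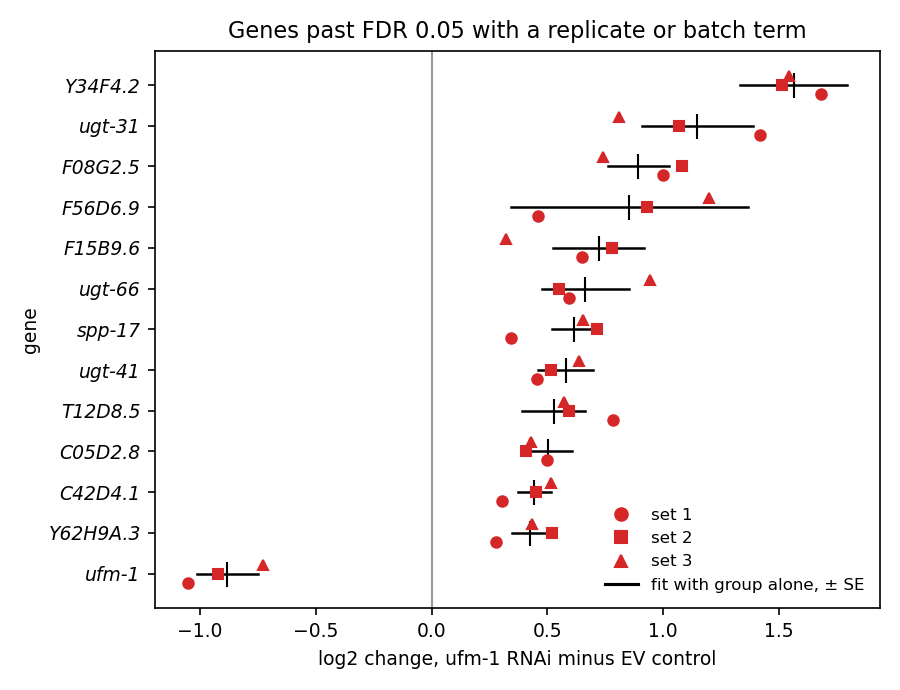
Log2 change between ufm-1 RNAi and EV control (horizontal axis) for the 13 genes (vertical axis) that passed with a replicate block or a batch term, with black lines for the fit with the group alone ± SE and red markers for each set. Values of ufm-1 were negative in all 3 sets (-1.05 to -0.73), and those of the other 12 genes lay above 0 in all 3.

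Of the 34 gene lists, 10 passed camera with the group alone, 6 upward and 4 downward. In that fit no list member passed over all genes, and adjusted over the list alone members passed only in UFMylation and DAF-16 class II. At an estimated correlation 0 lists passed with the group alone, the block or the batch term, and 0 in batch A alone. Without RNAi set 3 the fit with the group alone sets RNAi libraries of batch A against EV libraries of both batches. The fit to batch A alone, which also lacks that library, is therefore given beside it. Transcripts of the adult germline and oocytes were lower on ufm-1 RNAi, by a small amount shared over nearly the whole list. Of 69 genes 65 lay below 0, with a median log2 change of -0.17, and the list passed camera with the group alone (adjusted p = 1.08e-14, but 0.548 with an estimated correlation). Examples are chs-1, the eggshell chitin synthase, at -0.29 (SE 0.08), and cbd-1, an eggshell protein, at -0.28 (SE 0.08). Neither passed over all genes or over the list alone. With the replicate block, 28 members fell adjusted over the list alone, chs-1 and cbd-1 among them. The median was -0.13 in batch A, -0.29 in batch B and -0.09 without RNAi set 3, and the list passed in the fit to batch A alone (-0.12, adjusted p = 1.78e-08).

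Sperm genes were lower in the fit as a whole, with 59 of 61 below 0 and a median of -0.65 (camera adjusted p = 4.64e-09, but adjusted p = 0.561 with an estimated correlation). It was -0.30 without EV set 3 and -0.43 without EV set 4, and with the stricter filter it was -0.12 and did not pass (adjusted p = 0.253). The sets disagreed, at 0.39, -0.41 and -0.997, and the median was 0.06 within batch A (-0.07 in the fit to batch A alone, not past the test) and -0.93 within batch B. The RNAi group has fewer libraries of batch B, where sperm genes on EV were higher by a median of 1.04. This imbalance can lower the values with the group alone. With the replicate block 51 of 61 lay below 0 (median -0.44), and with the batch term 53 of 61 (-0.50). The major sperm protein genes msp-19 (-1.91, SE 0.41) and msp-33 (-1.48, SE 0.40) stood at only 1.21 and 1.92 CPM on EV. Near-identical copies share reads in that family, so single members are uncertain. With the replicate block 4 sperm genes fell adjusted over the list alone. RNA interference genes had 30 of 38 below 0 and a median of -0.09 (camera adjusted p = 0.000522, and 0.548 with an estimated correlation). This list includes alg-3 (-1.20, SE 0.38), an Argonaute of the male germline, and ppw-2 (-0.31, SE 0.11), another Argonaute. Its median was -0.08 in batch A, -0.15 in batch B and -0.06 without EV set 1, and without RNAi set 3 it was -0.04 and the call was lost (adjusted p = 0.0673). In batch A alone the list passed (-0.07, 0.00100). Vitellogenins, the yolk proteins made by the intestine, had a median of -0.11 and did not pass (camera adjusted p = 0.197; without EV set 2 the median was -0.15 and passed at 0.0496), with vit-1 at -0.23 and vit-2 at -0.14.

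Genes of embryos and larvae were higher, although the worms had been washed off daily to remove progeny. Larval cuticle and moulting genes had 24 of 31 above 0 and a median of 0.41 (camera adjusted p = 0.00406, and 0.558 with an estimated correlation). The cuticle collagen gene dpy-10 stood at 0.51 (SE 0.12) and ptr-4, a patched-related gene needed for moulting, at 0.55 (SE 0.14). With the replicate block 15 members rose and 2 fell, adjusted over the list alone. Those that fell were the collagen genes bli-1 (-1.14) and dpy-5 (-0.99), named after their values were seen. The list's median was 0.18, 0.18 and 0.85 in sets 1, 2 and 3, 0.19 in batch A and 0.65 in batch B. Without RNAi set 3 it was 0.04 and no longer passed (adjusted p = 0.475), nor did it with limma-voom (0.11, adjusted p = 0.105). In batch A alone it passed (0.20, 0.0460). Zygotic genes of the early embryo had 38 of 46 above 0 and a median of 0.25 (camera adjusted p = 0.00180, and 0.548 with an estimated correlation). Its members with the smallest p went opposite ways, sdz-27 at 0.28 and pal-1, a caudal homologue, at -0.23. The embryo median was 0.08 in batch A, 0.45 in batch B and 0.15 without RNAi set 3, and the list did not pass in batch A alone (adjusted p = 0.532).

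**Figure D4:**
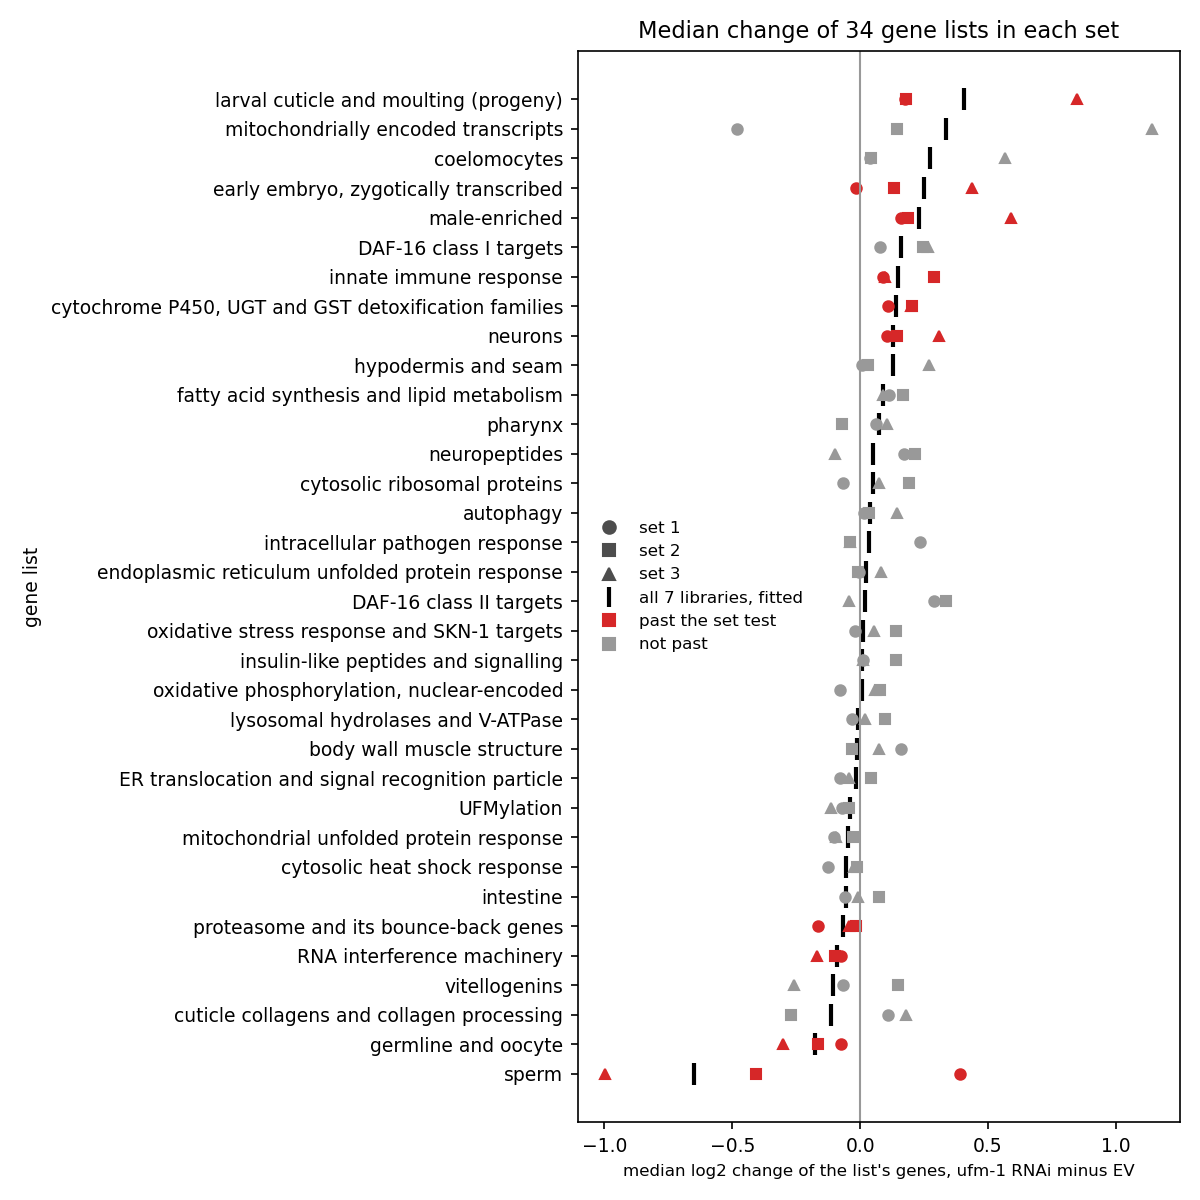
Median log2 change between ufm-1 RNAi and EV control (horizontal axis) for each of the 34 gene lists (vertical axis), with a marker shape for each set, a black bar for the fit over all 7 libraries, and red for lists past the camera test with preset correlation. Germline and oocyte medians lay below 0 in all 3 sets (-0.08, -0.16 and -0.30), detoxification medians above 0 in all 3 (0.11, 0.20 and 0.20), and sperm medians on either side.

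As lists, detoxification families and innate immune genes were higher, each by a median of 1.1-fold. Among the former, split by name stem after the results were seen, gst genes had a median of only 0.02 (17 of 30 above 0). It was 0.16 for ugt and 0.16 for cyp genes. The cytochrome P450, UGT and GST families had 193 listed genes, and among those measured 45 lay below 0 and the others above 0, with a median of 0.14 (camera adjusted p = 0.00201, and 0.581 with an estimated correlation). With the replicate block 2 members rose over all genes and 4 adjusted over the list alone. They were ugt-31, ugt-41, ugt-66 and ugt-25 (0.40), the last named after its value was seen. Batch A gave 0.14 and batch B 0.19, and without EV set 1 0.09, while without RNAi set 3 the median was 0.06 and the list did not pass (adjusted p = 0.108), nor did it with limma-voom (0.10, adjusted p = 0.0733). In batch A alone it passed (0.15, 0.000320). Innate immune genes had 35 of 49 above 0 and a median of 0.15 (camera adjusted p = 0.00592, and 0.548 with an estimated correlation), with the antimicrobial caenopore gene spp-1 at 0.53 (SE 0.11) and K08D8.5 at 0.47 (SE 0.13). Their median was 0.22 in batch A and 0.04 in batch B, and without RNAi set 2 the list did not pass (0.07, adjusted p = 0.235), nor did it in batch B alone (0.07, 0.747). With the block, 4 of its members rose adjusted over the list alone. The intracellular pathogen response did not pass (median 0.04, camera adjusted p = 0.740; batch A alone gave 0.09 and 0.0468), with pals-23 at 0.31 and pals-34 at 0.48. Oxidative stress and SKN-1 target genes did not pass either (median 0.01, camera adjusted p = 0.594), with sqrd-1 at 0.31 and the catalase gene ctl-1 at 0.45.

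Targets activated by the insulin pathway's transcription factor DAF-16 (class I) had 22 of 28 above 0 and a median of 0.16. They missed the threshold with the group alone (camera adjusted p = 0.0579) and passed with the replicate block (median 0.18, adjusted p = 0.00479, but 0.902 with an estimated correlation), and also without EV set 4 (0.20, adjusted p = 0.0197). They passed as well with DESeq2 size factors (0.0496), the stricter filter (0.0355), the batch term (0.0297) and in batch A alone (0.0171). In the blocked fit 7 members rose adjusted over the list alone. The metallothionein gene mtl-2 (0.36, SE 0.10) and the fatty acid desaturase gene fat-5 (0.38, SE 0.13) were among them. Class II targets, which DAF-16 activity lowers, did not pass as a list (median 0.02, camera adjusted p = 0.30). The sets disagreed, with medians of 0.29, 0.34 and -0.04, and the list passed in batch A alone (0.24, adjusted p = 0.000732) but not in batch B (-0.11, 0.304). Adjusted over the list alone, 3 of its 17 members rose with the group alone. They were spp-1, the insulin-like gene ins-7 (0.64, SE 0.16) and dod-23 (0.41, SE 0.11), the last named after its value was seen. Membership is that of the list as fixed beforehand, and the response of single members, such as spp-1, to DAF-16 was not checked. By set ins-7 stood at 0.92, 0.98 and 0.09. Insulin-like peptides and signalling genes did not pass (median 0.01, camera adjusted p = 0.918), with akt-2 at 0.24. Fatty acid and lipid genes lay just above the threshold with TMM scaling and the group alone (median 0.09, camera adjusted p = 0.0502). They passed under the 3 other scalings (adjusted p = 0.0496 with DESeq2 size factors, 0.0367 with library totals and 0.0326 with the upper quartile), but not at an estimated correlation (0.548). They also passed without EV set 3 (0.15), EV set 4 (0.12) or RNAi set 1 (0.15), with the stricter filter (adjusted p = 0.00704), with the batch term (0.0315) and in batch A alone (0.0171). With the block 9 of them rose adjusted over the list alone, among them the desaturase genes fat-2 (0.30), fat-5 (0.32) and fat-6 (0.32) and the lipid-binding protein gene lbp-3 (0.28).

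Of the stress pathways of protein folding, none passed camera as a list with the group alone. Median changes were 0.03 for the endoplasmic reticulum unfolded protein response (camera adjusted p = 0.799), -0.02 for translocation into that organelle (0.501), -0.05 for the cytosolic heat shock response (0.0579) and -0.05 for the mitochondrial unfolded protein response (0.144). The heat shock list passed with DESeq2 size factors (-0.07, adjusted p = 0.0496), without RNAi set 3 (-0.07, 0.0282), without EV set 2 (-0.06, 0.0315) or EV set 3 (-0.07, 0.0487), and with the batch term (-0.05, 0.0488). It also passed with limma-voom (-0.06, 0.0277) and in batch A alone (-0.08, 0.0147), but not at an estimated correlation (0.548). The median of the endoplasmic reticulum list lay at the 99.99th percentile of 10000 random lists matched on abundance and exonic length, which ran from -0.096 to -0.016 (middle 95%). That of the heat shock list lay at the 37.68th and that of the mitochondrial list at the 51.4th. Such random lists take no account of correlation between genes, so these percentiles do not decide whether a list changed. The endoplasmic reticulum median was -0.006, -0.010 and 0.080 in sets 1, 2 and 3, and -0.003 with the batch term. No gene of these folding pathways passed with the group alone or the block. Values were 0.32 (SE 0.08) for atf-4, a transcription factor of the integrated stress response, and -0.15 for gfat-1, an enzyme of hexosamine synthesis. The change was 0.23 for trap-2, of the translocon-associated complex. The myosin chaperone gene unc-45 stood at -0.15 and hsp-70 at -0.24, and the mitochondrial chaperone genes hsp-60 and hsp-6 at -0.22 and -0.20. Proteasome genes passed as a list by a small margin in size, with 33 of 36 below 0 and a median of -0.07 (camera adjusted p = 0.00106, and 0.548 with an estimated correlation). Its members rpn-1 and rpn-3 both stood at -0.13. The proteasome median was -0.08 in batch A, -0.04 in batch B and -0.04 without EV set 1, and without RNAi set 1 it was -0.02 and did not pass (adjusted p = 0.102), nor did it in batch B alone (0.118). Autophagy genes (median 0.04, camera adjusted p = 0.501; 99.76th percentile of the matched lists) and lysosomal genes (-0.01, 0.626) did not pass. Among them epg-2 and atg-2 stood at 0.47 and 0.16, the proton pump gene vha-18 at -0.21 and the cathepsin-like gene cpr-8 at 0.35.

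Neuron genes had 30 of 37 above 0 and a median of 0.13 (camera adjusted p = 0.00910, and 0.548 with an estimated correlation), with syd-2 at 0.24 and the GABA transporter gene unc-47 at 0.71. The neuron median was 0.15 in batch A, 0.25 in batch B and 0.20 without RNAi set 2, and without RNAi set 3 it was 0.07 and did not pass (adjusted p = 0.138), nor did it with limma-voom (0.06, adjusted p = 0.268) or in batch B alone (0.0766). In batch A alone it passed (0.15, 0.00154). Male-enriched genes, of which only 5 were measured, had a median of 0.23 (camera adjusted p = 0.0344, and 0.548 with an estimated correlation), 0.21 in batch A and 0.47 in batch B, with try-5 at 0.56 and clec-178 at 0.58. They lost the call with the replicate block (adjusted p = 0.0503), the batch term (0.0665), both other filters, limma-voom (0.162) and within either batch, and without EV set 1 (0.134), EV set 3 (0.0581), RNAi set 2 (0.0653) or RNAi set 3 (0.108). The medians of the neuron, male-enriched, RNA interference and proteasome lists lay at the 88.0th, 87.9th, 8.39th and 2.87th percentiles of 10000 random lists matched on abundance and exonic length. They were thus within the middle 95% that such lists gave.

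No other tissue list passed camera with the group alone. Medians were -0.01 for body wall muscle (adjusted p = 0.612), -0.05 for intestine (0.770), 0.07 for pharynx (0.778), 0.13 for hypodermis and seam (0.275), 0.27 for coelomocytes (0.120), 0.05 for neuropeptides (0.501) and -0.12 for cuticle collagens (0.0843). Without RNAi set 3 the collagen median was -0.66 (adjusted p = 7.16e-10) and that of muscle -0.15 (0.00085), both past the test, and that of hypodermis and seam was -0.03 (0.857). These shifts go with the imbalance of batches in that fit, since on EV batch B exceeded batch A by 0.77 for collagens and 0.55 for muscle. In batch A alone neither passed (-0.04, 0.113 for collagens and 0.06, 0.365 for muscle). Without EV set 1 both also passed (-0.28 and -0.08), and without EV set 2 the collagens did (-0.20). Collagens also passed with library totals (0.0317) and the upper quartile (0.0132), and with limma-voom both lists did. The collagen median lay at percentile 0 of the matched lists but was 0.05 with the block (0.408). Neuropeptides passed with the stricter filter (0.11, 0.0344) and in batch A alone (0.19, 0.000297). The hypodermis and seam median was 0.26 in batch B alone, where RNAi set 3 is the lone RNAi library. Members stood at 0.13 and 0.12 (act-4 and zyx-1, muscle), 0.36 and 0.34 (mtl-2 and fat-6, intestine), 0.27 and 0.83 (pqn-89 and pqn-13, pharynx), and 0.55 and 0.75 (ptr-4 and dpy-7, hypodermis). In RNAi sets 1, 2 and 3, pqn-13 stood at 3.44, 3.29 and 11.5 CPM and dpy-7 at 6.49, 6.79 and 13.9 CPM. Both changes thus rest largely on RNAi set 3. Further values were 0.38 and 0.55 (eya-1 and lgc-26, coelomocytes), 0.25 and 0.45 (nlp-77 and nlp-39, neuropeptides), and 0.56 and 0.51 (the collagen genes col-99 and dpy-10). Cytosolic ribosomal proteins had a median of 0.05 (adjusted p = 0.152), with rpl-25.1 at 0.30 and rpl-11.2 at 0.31. They passed without RNAi set 1 (0.14), with the stricter filter (adjusted p = 0.0156), with limma-voom (0.0307) and with the batch term (0.0312). Nuclear-encoded oxidative phosphorylation genes had a median of 0.01 (0.597), with sdha-2 at -0.14 and cyc-2.1 at 0.15. Mitochondrially encoded transcripts had a median of 0.34 (adjusted p = 0.0536), with ctc-1 at 0.51 and ctb-1 at 0.39. Their median was -0.48, 0.14 and 1.14 in sets 1, 2 and 3. The list passed without EV set 1 (0.58) or RNAi set 1 (0.47), with DESeq2 size factors (0.32, adjusted p = 0.0443), limma-voom (0.36, 0.00123), no filter beyond 1 read (0.33, 0.0487) and the stricter filter (0.37, 0.0355). It passed downward in batch A alone (-0.18, 0.015) and upward in batch B alone (1.11, 4.91e-08), where RNAi set 3 is the lone RNAi library, and was 0.07 without RNAi set 3. The pharynx and oxidative phosphorylation lists had medians and means above 0 while camera, which compares a list with all other genes, placed them lower, and the lysosomal list had a mean of 0.02 against a median of -0.01. With the replicate block, adjusted over the list alone, 2 intestine, 2 ribosomal protein, 2 coelomocyte and 1 lysosomal gene rose and 1 coelomocyte gene fell. Counts of unc-54, whose promoter drives the transgene, and of rol-6 can include transgene reads.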

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

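The batch term, the fits within batches (batch A also at an estimated correlation) and the fits with a block or batch term that leave out a library were chosen after the data were seen. The replicate block (paired fit) gave 4 genes higher and 1 lower, ufm-1 at -0.90 and 10 lists, and it changed no other call than those given in the results. With the group alone, the 3 other scalings, both filters, non-robust dispersions, composition genes left out and the 1.5-fold minimum kept 0 genes higher and 0 lower. Lists passing numbered 14, 12 and 12 with DESeq2 size factors, library totals and the upper quartile. DESeq2 gave 7 higher and 1 lower (ufm-1 at -0.90), and limma-voom 0 and 1 (ufm-1 at -0.99). The cause was not tested. Leaving out each library with the group alone gave 0 to 1 gene higher, 0 to 1 lower, ufm-1 at -1.06 to -0.76 and 8 to 13 lists, and the 2 genes, ufm-1 and C17H12.8, were called without RNAi set 3 alone. At a threshold of 0.1 there were 16 lists, with an estimated correlation 0 and with fry 0. The batch term gave 11 higher and 1 lower (ufm-1 at -0.85) and 13 lists, and batch A alone 12 and 1 (-0.99), with 0 lists at an estimated correlation. Batch B alone gave 922 and 965 (-0.64), where the lone RNAi library is assumed to vary like the 2 EV libraries, so that 1 degree of freedom carries the spread. With a library left out, the batch term gave 0 to 430 higher and 0 to 487 lower (22 and 6 without EV set 1, 430 and 487 without RNAi set 1, 12 and 1 without EV set 2 or 3, 1 and 1 without EV set 4, 7 and 1 without RNAi set 3, 0 without RNAi set 2). The replicate block gave 310 higher and 344 lower without EV set 1, 1 and 0 without EV set 2, 103 and 17 without EV set 3, 4 and 1 without EV set 4, 166 and 233 without RNAi set 1, 0 without RNAi set 2, and 100 and 17 without RNAi set 3. These fits have few residual degrees of freedom, and the cause was not tested. With the block, leaving out either library of a set leaves the same pairs, so those fits are not separate checks. Mitochondrially encoded transcripts turned from 0.34 to -0.18 in batch A alone. Of the values of named genes other than ufm-1 under alternatives, 1583 kept direction and side of the threshold, 62 came to pass, 9 moved and 0 reversed. For lists these numbers were 601, 54, 67 and 1, and 56 no longer passed. These totals do not include the fits with a block or batch term that leave out a library. Most of the 62 gene values came to pass in batch B alone, where RNAi set 3 is the lone RNAi library. The median of all genes moved from 0.013 to between 0.0019 and 0.049 under other scalings, and no list past the test changed sign under them. The planned comparison with the authors' fold changes was not run, because the table holds none. Depth limits genes near 1 CPM, such as Y34F4.2, unc-47 and the msp genes.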

Other observations

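The gene families below, the test of the difference between the batches, the count of lists with the group alone over splits that keep the batches, and the tests of RNAi set 3 alone, of progeny and of germline share were chosen after the results were seen. No library lay far from the rest of the EV group by Dixon's test in any of the 82 named values tested.

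Several large gene families, most of them on none of the lists above, had most members on one side of 0 on ufm-1 RNAi. Families were taken as genes that share a name stem, with at least 10 measured members, and 124 were tested with camera. Of these, 15 passed upward and 9 downward, and none held with an estimated correlation (smallest adjusted p = 0.604). The fbxb genes, which encode F-box proteins, had 83 of 90 members above 0 and a median log2 change of 0.45 (0.11, 0.35 and 0.68 in sets 1, 2 and 3). Transthyretin-related ttr genes had 41 of 47 above 0 and a median of 0.23 (0.14, 0.23 and 0.31). Cuticlin-like cutl genes had 21 of 22 above 0 and a median of 0.48 (0.22, 0.33 and 0.80). Nuclear hormone receptor genes had 139 of 184 above 0 and a median of 0.11 (0.069, 0.077 and 0.28). The lipase-related lips genes had 11 of 11 above 0, with a median of 0.25 (0.47, 0.26 and 0.41), and the ugt genes alone had 47 of 60 above 0, with a median of 0.16 (0.14, 0.21 and 0.27). Among families that passed downward, the msp genes had 0 of 23 above 0 and a median of -1.20, though the sets disagreed (0.25, -0.71 and -1.58). The him genes had 0 of 11 above 0 (median -0.17), the Integrator ints genes 0 of 11 (-0.11) and the proteasome rpn genes 0 of 13 (-0.083). Members of such families can share reads. The families were not compared with random lists matched on abundance and exonic length. Such random lists had a median of 0.093 for the detoxification list and -0.035 for the proteasome list. A trend with abundance and length can therefore be part of a family's change.

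Control worms of the 2 batches differed as well. On EV, the median gene in batch B lay above that in batch A by 1.04 (log2) for sperm, 0.77 for cuticle collagens and 0.55 for body wall muscle, and by -0.69 for mitochondrially encoded transcripts. These contrasts hold 2 libraries on each side and were not tested.

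For the count of 0 genes with the group alone, splits of the libraries into 3 and 4 decide nothing about chance, since any split gives at least 0 (35 of 35). The highest other split gave 1321. That split put EV 3, EV 4 and RNAi 3 on one side, which is the division into batches, and the next gave 592. A difference between batches may therefore add to the spread in the fit with the group alone. It can also shift the values of that fit, since the RNAi group has fewer libraries of batch B than the EV group. For the 10 lists past the set test, 15 of the 35 splits gave as many and the highest other gave 17, so chance is not excluded for the number of lists. Some of these splits follow the batches. Of the 18 that keep the group sizes in both batches, 9 gave as many lists with the group alone (highest other 14). With the batch term 13 lists passed, and 2 of the 18 gave as many (highest other 15). For the 10 lists with the replicate block, 4 of 4 swaps of the groups within sets gave as many (highest other 12). The 18 splits and the 4 swaps are too few for a share under 0.05. With the replicate block the real grouping called 5 genes and the highest of the other swaps within sets 0, but 1 in 4 swaps is the smallest share possible. With the batch term the real grouping called 12 genes and the highest other 0, where 1 in 18 is the smallest share, so these splits are too few to decide.

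Germline and oocyte genes were lower in all 3 sets. The list's median lay at percentile 0 of 10000 random lists matched on abundance and exonic length (-0.175 against a random median of -0.067). These random lists take no account of correlation between genes, which camera estimated at 0.318 for the germline list. Their spread can thus be too narrow, so the percentile does not decide about a general trend with abundance and length. A role of RNAi set 3 alone stays open. It was first tested without that library in the fit with the group alone (median -0.0945), which mixes the batches. After both values were seen, the fit to batch A alone took its place. There the median was -0.125 and the list passed at the preset correlation but not at an estimated one. This lies below the bound of -0.1 by less than the SE over sets 1 and 2 (0.0440), so 2 sets do not decide it, although both were negative. A lower germline share in worms fed ufm-1 RNAi, the biological explanation, may also account for the values but was not tested.

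Larval and embryo genes were higher, most of all in RNAi set 3. The larval median lay at percentile 100 of the matched lists (0.41 against a random median of 0.075). The correlation between its genes was estimated at 0.205, so this percentile does not decide about the trend with abundance and length either. Carried-over progeny, more abundant among the RNAi pools, may account for both lists. The prediction set for it was a rise of both in each set, and the lowest of the 6 medians was -0.0172 (embryo, set 1). Carried-over progeny could differ between pools and raise the lists in 1 set alone, so that value does not count against it. Progeny and a change within the adults cannot be told apart with 3 sets. An effect of ufm-1 RNAi on the timing or number of progeny stays open, untested.

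Among the detoxification families the gst genes hardly changed with the group alone (median 0.02, against 0.16 for ugt and 0.16 for cyp genes). Taken as a list, the families were higher in all 3 sets, at percentile 98.36 of the matched lists. Those lists had a median of 0.093 against 0.140 for the families, so part of the rise can be the trend with abundance and length. The correlation between the families' genes was estimated at 0.132, so the percentile does not decide whether the trend is the whole cause. A smaller germline would raise all somatic genes alike. The families' median exceeded that of the intestine list by 0.169 (mean over 3 sets, SE 0.0234), more than the 2 SE set as the bound against that explanation. Part of that difference is the trend and the low intestine list, which lay at percentile 1.29 of its own matched lists, so it does not decide. Matched random lists differed by 0.0844, and the difference left was 0.0847 (SE 0.0167), again more than 2 SE above 0. With the group alone the intestine list lay at -0.055 against a random median of 0.020. The difference left can thus rest on the low intestine list, so it does not decide about a smaller germline together with the trend. Other somatic lists differed. With the group alone neurons (0.13) and hypodermis and seam (0.13) had medians near that of the families. Body wall muscle (-0.01) and pharynx (0.07) lay lower, as did intestine, and coelomocytes (0.27) higher. The hypodermis median was 0.009, 0.029 and 0.270 in sets 1, 2 and 3, so it rests largely on RNAi set 3. The families' call was lost without RNAi set 3 in the fit with the group alone. In batch A alone it was kept at the preset correlation but not at an estimated one (camera adjusted p = 0.710). Since chance is not excluded by the splits of the lists, a response of these genes to ufm-1 RNAi is a hypothesis only.

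RNAi against ufm-1 might also lower tomm-7, the nearest gene downstream on the same strand (chromosome III, 7859613 to 7860159), 101 bp from it. Its log2 change was -0.338 (SE 0.169) and negative in 3 of 3 sets, which meets the value set beforehand for that hypothesis. It did not pass in edgeR with the group alone (adjusted p = 0.580) or the block (0.305). The upstream genes on the opposite strand, coq-5 (-0.18) and tag-307 (-0.23), were also lower in 3 of 3 sets and did not pass either, so the value is not particular to the downstream gene.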
